A study of Homo sapiens with 3 samples.

How the data were processed

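Normal human bronchial epithelial cells were left untreated or exposed to 50 or 100 µg/mL of PM2.5 (airborne particles of the fine size class), and 1 RNA-seq library per dose was sequenced, so the 3 libraries form 3 groups of 1. Per the labels, total RNA was taken with Trizol and 1 µg entered an Illumina TruSeq RNA preparation. Reads were aligned with TopHat2 to genome build hg19, per the submitters' processing notes. The counter, the gene annotation, the handling of duplicates and the exposure time are not given in the sources used here. The deposited table held raw read counts per gene for 52864 entries, per the file headers. It also held RPKM values (reads scaled by gene length and library size), which the authors scaled by each library's own sum of gene counts. Recomputing RPKM from count, length and that sum returned the deposited values. The deposited length was the full gene span with introns for 75.5% of all entries and 94.2% of coding entries, so RPKM runs low for long genes.

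The sums of gene counts were 61153519 for control, 40989623 at 50 and 54721734 at 100. These are sums over genes and not reads, because overlapping entries held the same reads. Entries of the ribosomal RNA contig took 41.1% of the sum in control, 52.9% at 50 and 38.0% at 100. A floor of 3 counts equals 0.0491 CPM (counts scaled to a common library size) in control, 0.0825 at 50 and 0.0445 at 100. Of 13296 entries with an Ensembl identifier, 12151 were given a symbol, and 28 gene names had been turned into dates. The labels do not settle whether counting used strand. Of 14 pairs of entries on opposite strands with an overlap of at least 95% and 100 reads, the entry with fewer reads had a median of 16.9% of the reads of the other. MGAT2 had 1592 control reads and the entry opposite to it 1314. Antisense and overlapping genes, gene copies and pseudogenes are therefore uncertain.

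With 1 library per group no test was made, and no p-value is given. The choices in this paragraph were made before the data were examined. The main measure was log2 of the ratio of RPKM values after adding 0.5, over genes with a mean RPKM of at least 1, and genes at least 2-fold apart were counted. Long noncoding RNAs, by the class column, entered at a mean RPKM of at least 0.5. Gene lists needed at least 5 members past the filter. The median of a list was set against 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. The genes to name were, per dose against control, the 12 highest and 12 lowest by the main measure, for 100 against 50 the 5 highest and 5 lowest, the 10 with the largest change shared by both doses, 2 to 4 members per list with the largest change at 100, and the 5 highest and 5 lowest noncoding RNAs. Bare clone, LOC and small RNA names were not eligible. Y-linked genes, XIST and TSIX were left out of all gene sets.

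Alternatives were a pseudocount of 0.1 or 1, no filter or a mean RPKM of at least 5, rescaling to a common total (TPM), centring on the median gene, trimmed mean (TMM) scaling of RPKM, CPM with TMM factors and a prior of 2 reads, leaving out small and structured RNA genes, thresholds of 1.5-fold and 3-fold, list means, and lists without shared members. The TMM factors on counts were 1 for control, 0.887 at 50 and 1.23 at 100. The CPM measure kept 15300 genes where RPKM kept 5875. Its filter at a mean of 1 and the minimum of 200 bases for long noncoding RNAs were set after the data were opened. List medians are given in CPM first, a decision made after the values were seen, because RPKM left 13 of 33 lists under 5 members. The tests on lists in the closing section also use CPM. Folds of named genes are ratios of TMM-scaled read counts with exact conditional (Clopper-Pearson) 95% intervals, which cover counting error only. List examples were also taken from members that passed only the CPM filter, by size of change, after their values were seen. Alternatives chosen after seeing the data were a filter on the 2 libraries compared, folds adjusted for gene span in 20 bins, and random lists matched on expression and span in bins of 10 by 10.

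The measures were tested on simulated data with 200 changed genes. Counts were drawn with counting noise only from a single pooled profile, and folds were centred on the median gene before calling. The runs therefore leave out differences between cultures or preparations and the shift of the median gene in the deposited RPKM. They give no rate of false calls for the uncentred main measure. For 100 against control in CPM, run on 15368 genes, 66 of 66 genes changed 3-fold and 61 of 61 changed 4-fold were called at least 2-fold apart, against 0 of 67 changed 1.5-fold and 0 of 15174 unchanged genes. For the same comparison in RPKM, on 5801 genes, centred folds called 61 of 66 genes changed 3-fold and 12 of 5611 unchanged genes. For 50 against control in RPKM, on 5832 genes, they called 52 of 56 genes changed 3-fold and 31 of 5648 unchanged genes. Of 100 simulated lists of 20 unchanged genes, the number outside the central 95% of random lists was 1 at 50 and 10 at 100 by RPKM, and 3 at 50 and 7 at 100 in CPM. Lists just outside their range are therefore uncertain. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.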

Results

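RNA from normal human bronchial epithelial cells, the cells that line the large airways, was sequenced without exposure and after exposure to 50 or 100 µg/mL of PM2.5. Each dose had 1 library, so no difference below has a replicate check. The sums of gene counts were 61153519 for control, 40989623 at 50 and 54721734 at 100 µg/mL. The comparisons ask which coding and long noncoding RNAs differ with PM2.5 and whether they follow its dose. Folds of single genes are ratios of TMM-scaled read counts, with 95% intervals for counting error in brackets, and positions are on hg19. The median gene by deposited RPKM lay at a log2 ratio of -0.36 at 50 and -0.04 at 100 against control, so directions are given relative to the TMM scaling unless RPKM is named. Medians of gene lists are in CPM, read counts per library size with TMM factors. This measure was set down beside RPKM before the data were opened, but was put first after the values were seen, because RPKM left 13 of 33 lists under 5 members and CPM 5; RPKM medians or calls are given beside it for lists with at least 5 members by RPKM that are named. In data simulated with counting noise only, 7 of 100 lists of unchanged genes in CPM and 10 of 100 by RPKM fell outside the central 95% at 100. CYP1A1, HMOX1, STC2 and all other list members outside the naming rule were chosen after their values were seen.

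At 100 µg/mL, many but not all measured targets of the aryl hydrocarbon receptor and of NRF2 were higher than in control. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 15, 75011883 to 75017951), had 15 reads in control and 551 at 100, a ratio of 33.3 [20 to 59.9]. Of 9 measured aryl hydrocarbon receptor targets, 5 were at least 1.5-fold higher and 1 at least 1.5-fold lower. ALDH3A1, an aldehyde dehydrogenase (chromosome 17, 19641297 to 19651746), had a ratio of 2.53 [2.28 to 2.81], UGT1A6 of 2.62 [1.90 to 3.66] and CYP1B1 of 1.86 [1.34 to 2.63]. Reads of UGT1A6 may be shared with other UGT1A entries at the same locus. CYP2S1 was 1.52-fold lower [1.25 to 1.86], and AHRR, the receptor's repressor, was 1.02-fold lower [0.975 to 1.06]. The median log2 fold change of the list was 0.84, where the central 95% of random lists ran from -0.42 to 0.35. By RPKM the list had only 4 members past the filter and was not scored.

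Targets of NRF2, the transcription factor of the antioxidant response, had a median of 0.63 at 100, where random lists ran from -0.32 to 0.15; by RPKM it was 0.46 over 11 members, above a range of -0.21 to 0.12. Of 22 members, 12 were at least 1.5-fold higher and 0 lower. HMOX1, which breaks down heme (chromosome 22, 35777060 to 35790207), had 170 reads in control and 903 at 100, a ratio of 4.82 [4.09 to 5.71]. The transporter ABCC2 had a ratio of 2.73 [2.26 to 3.33], malic enzyme ME1 of 2.56 [2.36 to 2.78], and GCLM, a subunit of the enzyme that starts glutathione synthesis, of 2.21 [1.97 to 2.48]. NQO1, held by both lists, had a ratio of 1.79 [1.67 to 1.92]. FTH1, the ferritin heavy chain that stores iron, had a ratio of 1.52 [1.5 to 1.54], and TFRC, the transferrin receptor that imports iron, was 1.94-fold lower [1.91 to 1.98].

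**Figure D1:**
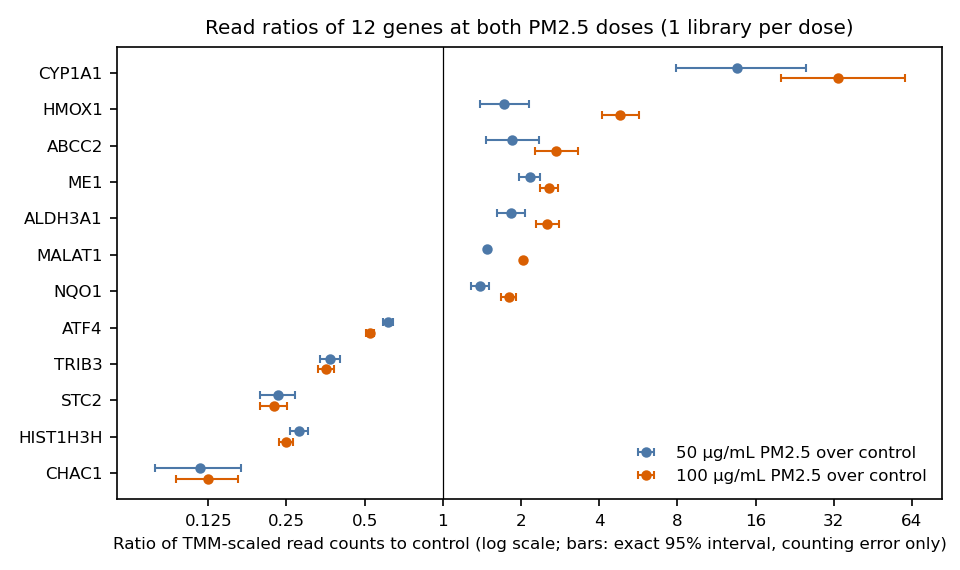
Ratios of TMM-scaled read counts to control for 12 genes at 50 and 100 µg/mL of PM2.5 on a log axis, with 1 library per dose and bars for the exact 95% interval of counting error. CYP1A1 lies highest, at 13.6 and 33.3, and CHAC1 lowest, 8.63-fold and 8.0-fold lower.

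Genes of the unfolded protein and integrated stress response were lower at 100. The median of 23 members was -0.82, where random lists ran from -0.35 to 0.10, and 14 members were at least 1.5-fold lower and 0 higher. By RPKM the median was -0.44 over 17 members, below a range of -0.20 to 0.08. CHAC1, which degrades glutathione (chromosome 15, 41245636 to 41248717), had 450 reads in control and 62 at 100, 8.0-fold lower [6.13 to 10.6]. STC2 was 4.48-fold lower [3.98 to 5.05], TRIB3 was 2.82-fold lower [2.63 to 3.03], and ATF4, the transcription factor of this response, was 1.90-fold lower [1.83 to 1.98]. The chaperone HSPA5 was 1.28-fold lower [1.24 to 1.31].

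Histone genes of the replication-dependent kind, whose mRNAs are made in S phase and end without a poly(A) tail, were also lower. All 29 measured members of the list were at least 1.5-fold lower and 25 at least 2-fold lower at 100, with a median of -1.30 where random lists ran from -0.32 to 0.08. By RPKM the median was -1.07 over 27 members, below a range of -0.25 to -0.02. Lowest by RPKM, outside the list, was HIST1H2AL (chromosome 6, 27833107 to 27833576), with 2361 reads in control and 535 at 100, 4.87-fold lower [4.43 to 5.35], and next HIST1H3J, 4.76-fold lower [4.21 to 5.38]. Histone genes are near-identical copies, so reads may be split between them. Among 28 cell cycle genes, 4 were at least 1.5-fold lower and 1 higher, with a median of -0.33, below the range of -0.27 to 0.15; by RPKM it was -0.08, inside its range. PLK1 was 1.72-fold lower [1.55 to 1.92], MKI67 was 1.04-fold lower [0.991 to 1.10], and CENPF had a ratio of 1.72 [1.57 to 1.90]. Structured RNAs without a poly(A) tail had a median of -0.46 over 18 members, below the range of -0.42 to 0.02; by RPKM it was -0.14, inside its range.

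Further lists lay below the range of random lists at 100 in CPM. The 18 measured TGF-beta and mesenchymal genes had a median of -0.59, with the matrix protein FN1 1.80-fold lower [1.68 to 1.94] and TAGLN 1.73-fold lower [1.61 to 1.86]. The rest of this list of 24 fell under the filter, so its median does not describe them. VIM had 12, 9 and 9 reads in control, at 50 and at 100, SNAI1 32, 13 and 28, and ZEB1 10, 28 and 51. ZEB2 had 1, 2 and 18, TWIST1 0, 0 and 16, and SPARC 0, 0 and 1. The 15 airway basal cell markers had a median of -0.49 (by RPKM -0.34, also below its range), with laminin LAMB3 1.72-fold lower [1.67 to 1.78] and integrin ITGB4 1.70-fold lower [1.66 to 1.75], while DST had a ratio of 1.77 [1.71 to 1.83]. DST spans 497 kb, and adjusted for span its log2 fold change was 0.11 instead of 0.82. EGFR ligands and remodelling genes had a median of -0.55 over 9 members, immediate early genes of -0.45 over 14 and cytosolic ribosomal proteins of -0.50 over 34. The EGFR list holds 20 genes, and most of its ligands and MMP genes fell under the filter, so its median does not describe them. AREG had 14, 2 and 4 reads in control, at 50 and at 100, and EREG 0, 0 and 2. BTC had 18, 11 and 14, and EPGN 20, 29 and 64. By RPKM immediate early genes (-0.16) and ribosomal proteins (-0.20) lay inside their ranges, and the TGF-beta and EGFR lists had under 5 members. Inside the range of random lists lay inflammatory cytokines and NF-kB targets (median -0.13, 15 members), type I interferon genes (-0.07, 15 members), p53 targets (-0.21, 21 members) and heat shock chaperones (0.04, 15 members). So did cholesterol synthesis (-0.13), hypoxia and glycolysis (-0.28), epithelial junctions (-0.36), autophagy and lysosome genes (-0.20), ferroptosis and iron handling (0.03), fatty acid and PPAR targets (-0.21), the nuclear-encoded respiratory chain (-0.33), metallothioneins (-0.41), housekeeping genes (-0.35) and named long noncoding RNAs (-0.13). By RPKM heat shock chaperones (0.19), cholesterol synthesis (0.13), ferroptosis and iron handling (0.24) and named long noncoding RNAs (0.11) lay above their ranges. Inside their ranges by RPKM were p53 targets (-0.12), hypoxia and glycolysis (-0.04), epithelial junctions (-0.15), autophagy and lysosome genes (0.04), fatty acid and PPAR targets (-0.12), the respiratory chain (-0.03), metallothioneins (-0.11) and housekeeping genes (-0.10). The table held no mitochondrially encoded gene. Within the cytokine list, TNFAIP3 was 1.94-fold lower [1.61 to 2.35] and BIRC3 had a ratio of 2.23 [1.55 to 3.24]. Several secreted cytokines of that list fell under the filter. IL6 and CCL2 had 0 reads in each library, IL8 had 8, 3 and 3 in control, at 50 and at 100, and IL1A 21, 25 and 56. The list median therefore says nothing about them. The same limit holds for the type I interferon list of 28 genes, of which IFIT1, MX2, OAS2, IFI6, IFI27, IFI44L and RSAD2 were among those under the filter. Markers of other cell types were mostly near the floor: 3 of 13 fibroblast, 3 of 16 leukocyte, 3 of 10 endothelial and 2 of 10 alveolar type 2 markers had a mean of at least 1 CPM. Of 18 airway basal cell markers, 15 reached that mean. KRT14 (24, 11 and 7 reads in control, at 50 and at 100), KRT6A (9, 12 and 20) and KRT6B (6, 0 and 5) did not. Squamous, secretory and ciliated markers had 6, 7 and 5 members past that filter, and each list lay inside its random range.

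**Figure D2:**
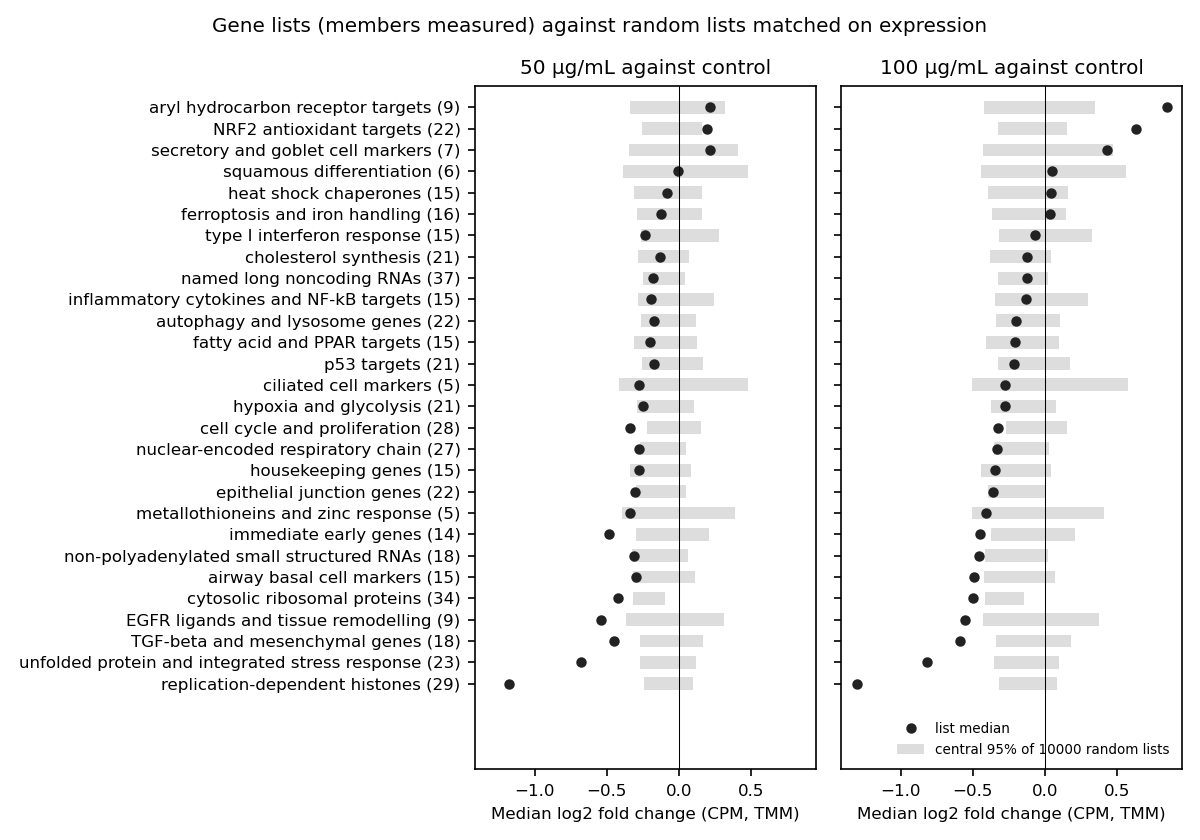
Median log2 fold change in CPM of 28 gene lists, with the number of measured members in brackets, at 50 and 100 µg/mL against control (points), and the central 95% of 10000 random lists matched on expression (bars). At 100 the aryl hydrocarbon receptor and NRF2 lists lie above their bars, at 0.84 and 0.63, and the histone list lies lowest, at -1.30.

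Fold changes followed gene span at both doses, and this stands beside each list above. Across 12118 coding genes, Spearman's rho between span and log2 fold change was 0.57 at 50 and 0.58 at 100; genes are not independent replicates. At 100 the median was -0.45 in the shortest 10% of coding genes and 0.57 in the longest 10%, where 290 of 1211 genes were at least 2-fold higher. Against random lists matched also on span, a comparison chosen after seeing the data, the aryl hydrocarbon receptor and NRF2 lists stayed above and the histone, stress response, TGF-beta, EGFR ligand and basal cell lists below the central 95% at 100. The medians of ribosomal proteins, immediate early genes, structured RNAs and cell cycle genes lay inside it. Heat shock chaperones, cholesterol synthesis, ferroptosis and iron handling, and named long noncoding RNAs lay above it.

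**Figure D3:**
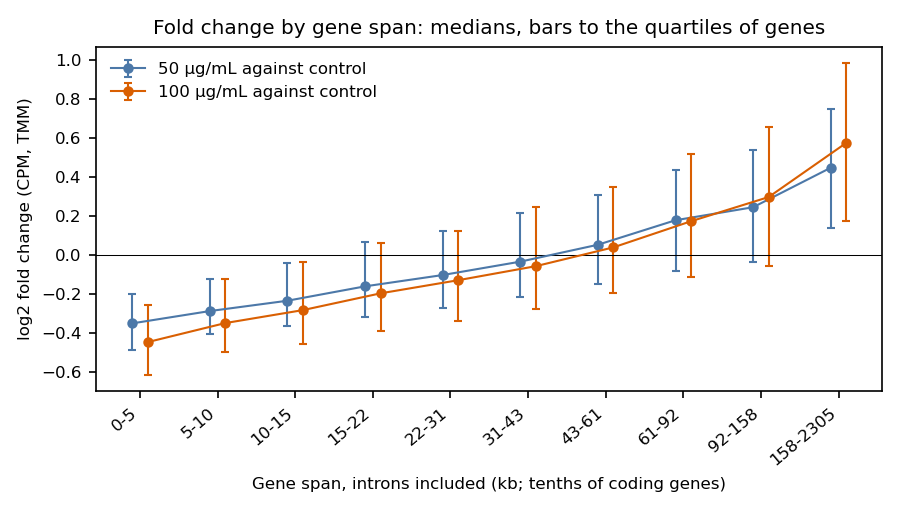
Median log2 fold change (points) and quartiles of genes (bars) in 10 equal groups of 12118 coding genes ordered by gene span in kb, at 50 and 100 µg/mL of PM2.5 against control. At 100 the medians run from -0.45 in the shortest group to 0.57 in the longest.

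By the main measure, 64 of 5875 genes were at least 2-fold higher and 49 lower at 100 than in control. Centring on the median gene gave 77 higher and 49 lower, TMM scaling of RPKM gave 33 higher and 82 lower, and CPM gave 767 higher and 132 lower among 15300 genes. By RPKM 41 of the 64 higher genes were small or structured RNA genes, and only 2 were coding. Besides ALDH3A1, the highest eligible coding genes were ALPP, an alkaline phosphatase with a close paralog, at 1.97 [1.89 to 2.06], and AKR1C1, at 1.91 [1.52 to 2.40]. All of the 12 lowest eligible genes but CHAC1 were histone genes.

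Long noncoding RNAs were the class named in the design. Of 2109 past the filter, by RPKM 24 were at least 2-fold higher and 2 lower at 100, or 1.23%. Among coding genes of matched expression the share was 0.601%. By RPKM at 50, 9 were higher and 31 lower, or 1.90% against 0.819%. Genes in general lay low by RPKM at 50: the median log2 ratio was -0.26 in noncoding and -0.29 in coding genes. In CPM 106 of 1965 noncoding RNAs were higher and 27 lower at 100, and 68 higher and 18 lower at 50. The direction at 50 thus depended on the scaling. In CPM fewer noncoding than expression-matched coding genes were apart at 100, 6.77% against 8.91%. The match left out gene span. Over all 12118 coding genes 552 were higher and 97 lower, a smaller share than in noncoding RNAs. Of those higher, 290 lay in the longest 10% by span. Whether noncoding RNAs differ from coding genes thus depended on the genes they were set against. MALAT1, a nuclear RNA (chromosome 11, 65265224 to 65273940), had 181270 reads in control and 407378 at 100, a ratio of 2.04 [2.03 to 2.05]. The neighbouring nuclear RNA NEAT1 had a ratio of 1.71 [1.66 to 1.77], and BCYRN1, with 5 and 23 reads, of 4.17 [1.55 to 14.1]. TAB3-AS1 (ENSG00000231542.1), antisense by its class, had 2 and 19 reads, a ratio of 8.62 [2.08 to 76.3], and PLCG1-AS1 (ENSG00000226648.1) was 2.46-fold lower [1.84 to 3.32]. Antisense entries are uncertain because the use of strand is not settled.

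At 50 µg/mL some xenobiotic and antioxidant genes were higher than in control, and the stress response and histone lists were lower. At least 1.5-fold higher were 3 of 9 aryl hydrocarbon receptor targets and 5 of 22 NRF2 targets, and 1 in each list was at least 1.5-fold lower. CYP1A1 had 121 reads, a ratio of 13.6 [7.91 to 25], ALDH3A1 a ratio of 1.83 [1.61 to 2.07], and HMOX1 of 1.72 [1.39 to 2.14]. NRF2 targets had a median of 0.19, where random lists ran from -0.26 to 0.16. By RPKM it was -0.19, above a range of -0.53 to -0.23. The aryl hydrocarbon receptor list, with a median of 0.21, lay inside its random range of -0.34 to 0.32 but above the -0.35 to 0.10 of lists matched also on span. CHAC1 was 8.63-fold lower [5.99 to 12.9], STC2 was 4.32-fold lower [3.72 to 5.04] and TRIB3 was 2.72-fold lower [2.49 to 2.97]. The stress response list had a median of -0.68 (RPKM -0.77) and the histone list of -1.18 (RPKM -1.26), with 23 of 29 histone genes at least 2-fold lower. Also below their ranges at 50 were cell cycle genes (-0.34; RPKM -0.42, also below) and ribosomal proteins (-0.42; RPKM -0.59, also below). In CPM so were TGF-beta (-0.45), EGFR ligand (-0.54), immediate early (-0.49), epithelial junction (-0.30) and respiratory chain (-0.28) lists. By RPKM the immediate early (-0.53), epithelial junction (-0.48) and respiratory chain (-0.40) lists lay inside their ranges, and the TGF-beta and EGFR ligand lists had under 5 members. Against lists matched also on span, epithelial junctions and the respiratory chain lay inside in CPM, basal cell markers (-0.30) below, and heat shock chaperones (-0.08) and cholesterol synthesis (-0.13) above. By RPKM cholesterol synthesis (-0.27) lay above its range, and basal cell markers (-0.51) and heat shock chaperones (-0.31) inside theirs. MALAT1 had a ratio of 1.48 [1.47 to 1.49]. By the main measure 29 genes were at least 2-fold higher and 118 lower, against 74 and 44 when centred on the median gene, 40 and 92 with TMM-scaled RPKM and 376 and 110 in CPM.

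At 100 against 50 µg/mL, 5 of 22 NRF2 targets and 2 of 9 aryl hydrocarbon receptor targets were at least 1.5-fold higher and 0 lower. HMOX1 had a ratio of 2.80 [2.38 to 3.31], CYP1A1 of 2.46 [2.01 to 3.01] and SLC7A11, the cystine importer, of 1.92 [1.65 to 2.25]. NRF2 targets had a median of 0.34, where random lists ran from -0.12 to 0.07; by RPKM it was 0.67, above 0.21 to 0.45. Aryl hydrocarbon receptor targets had a median of 0.23, where random lists ran from -0.18 to 0.16. Ferroptosis and iron handling genes (0.13) also lay above their range, and histones (-0.13) and structured RNAs (-0.23) below. By RPKM heat shock chaperones (0.52) lay above and these 3 lists inside. Against lists matched also on span, histones and structured RNAs lay inside in CPM, and heat shock chaperones (0.051), cell cycle genes (0.050) and cholesterol synthesis (0.013) above. Cell cycle genes (0.37) and cholesterol synthesis (0.39) lay inside their ranges by RPKM. CHAC1 had a ratio of 1.08 [0.690 to 1.72] and STC2 was 1.04-fold lower [0.865 to 1.24], so counting error alone could give either difference. With 1 library per dose, these values do not show whether the doses differ. RPL9P8, a ribosomal protein pseudogene, had 86 reads in control, 0 at 50 and 177 at 100. By the main measure 83 genes were at least 2-fold higher and 18 lower at 100 than at 50, against 34 and 38 when centred, 29 and 42 with TMM-scaled RPKM and 38 and 18 in CPM.

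Genes at least 2-fold from control in the same direction at both doses numbered 53 by the main measure, with 15 higher and 38 lower, against 35 with the 50 library and 25 with the 100 library as the odd one out. Independent lists would share 0.316 higher and 0.984 lower genes. Unchanged simulated libraries, drawn with counting noise only, shared 3.35 and 1.75. In CPM 323 were higher and 63 lower at both doses, where independent lists would share 18.8 and 0.949. Both doses share the control library, so agreement above independence arises without any effect. In CPM control was the odd one out in 386 genes, the 50 library in 8 and the 100 library in 32. A control library that deviated alone would give this order too. By RPKM the correlation of the log2 fold changes across genes was 0.67, against 0.43 in simulated unchanged libraries, and the covariance 0.0762 against 0.0112. In CPM the correlation was 0.87 against 0.44, and the covariance 0.203 against 0.00643. The simulated libraries hold no difference between cultures or preparations, so they do not show what unchanged cultures would give. Part of the excess over them may come from the shared control library, which cannot be split. Of 113 genes at least 2-fold from control at 100, 54 had the 50 value between control and 100, and in CPM 811 of 899. Choosing genes by the gap between control and 100 itself favours a value in between, so these counts do not show a dose order.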

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

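The alternatives adjusted for gene span and the filter on the 2 libraries compared were chosen after seeing the data. The filter at a mean of 1 within the CPM alternative and the minimum of 200 bases for long noncoding RNAs were also set after the data were opened; the other alternatives were planned. The counts under the filter on the 2 libraries compared stayed within 1.5 times those reported. With 0.1 RPKM added, the counts were 49 higher at 50, 128 higher at 100, 150 higher at 100 than at 50, 108 stepwise and 121 noncoding. With 1 RPKM added, the counts were 19 higher at 50, 49 higher at 100 than at 50, 11 lower at 100 than at 50 and 11 noncoding. With no filter, the counts were 106 higher at 50, 203 lower at 50, 220 higher at 100, 97 lower at 100, 250 higher at 100 than at 50, 55 lower at 100 than at 50, 111 in the same direction at both doses and 153 stepwise. At a mean RPKM of at least 5, the counts were 5 higher at 50, 62 lower at 50, 15 higher at 100, 31 lower at 100, 22 higher at 100 than at 50, 3 lower at 100 than at 50, 31 in the same direction at both doses, 14 stepwise and 5 noncoding. Rescaled to a common total (TPM), the counts were 94 higher at 50, 51 lower at 50, 172 higher at 100, 33 lower at 100 than at 50, 143 stepwise and 112 noncoding. Centred on the median gene, the counts were 74 higher at 50, 44 lower at 50, 34 higher at 100 than at 50, 38 lower at 100 than at 50 and 88 stepwise. With trimmed mean scaling of RPKM, the counts were 33 higher at 100, 82 lower at 100, 29 higher at 100 than at 50, 42 lower at 100 than at 50 and 91 stepwise. With TMM-scaled CPM, the counts were 376 higher at 50, 767 higher at 100, 132 lower at 100, 38 higher at 100 than at 50, 386 in the same direction at both doses, 811 stepwise and 133 noncoding. Without small and structured RNA genes, the counts were 7 higher at 50, 23 higher at 100, 28 higher at 100 than at 50, 3 lower at 100 than at 50 and 23 stepwise. At 1.5-fold, the counts were 91 higher at 50, 822 lower at 50, 263 higher at 100, 146 lower at 100, 536 higher at 100 than at 50, 46 lower at 100 than at 50, 179 in the same direction at both doses, 212 stepwise and 221 noncoding. At 3-fold, the counts were 8 higher at 50, 21 lower at 50, 15 higher at 100, 9 lower at 100, 15 higher at 100 than at 50, 4 lower at 100 than at 50, 12 in the same direction at both doses, 10 stepwise and 1 noncoding. With RPKM folds adjusted for gene span, the counts were 62 higher at 50, 56 lower at 50, 32 higher at 100 than at 50, 40 lower at 100 than at 50 and 85 stepwise. With CPM adjusted for gene span, the counts were 258 higher at 50, 74 lower at 50, 475 higher at 100, 98 lower at 100, 37 higher at 100 than at 50, 246 in the same direction at both doses, 498 stepwise and 126 noncoding. The scalings differ by the shift of the median gene, and CPM keeps long genes that RPKM drops; other causes were not tested. No paired analysis was possible because each group has 1 library.

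Of 940 recomputed folds of named genes, 708 stayed within counting error, 232 moved further and 0 changed sign among those at least 2-fold apart. Of 482 recomputed list medians, 304 moved by less than 50% of the width of the random range, 160 moved further and 18, all of lists outside that range, changed sign. Random lists move with the scaling too, so a changed sign does not by itself place a list inside its range. The median of the NRF2 antioxidant targets, 50 against control, was -0.19 and became 0.00041 with no filter, 0.18 with TPM, 0.17 with median centring, 0.19 with CPM, 0.17 with span-adjusted RPKM and 0.26 with span-adjusted CPM. The median of the heat shock chaperones, 100 against control, was 0.19 and became -0.057 with trimmed mean scaling. The median of the cholesterol synthesis genes, 50 against control, was -0.27 and became 0.066 with TPM, 0.10 with median centring and 0.054 with span-adjusted RPKM. The median of the cholesterol synthesis genes, 100 against control, was 0.13 and became -0.16 with trimmed mean scaling, -0.13 with CPM and -0.0031 with span-adjusted CPM. The median of the ferroptosis and iron handling genes, 100 against control, was 0.24 and became -0.070 with trimmed mean scaling and -0.052 with the mean of members. The median of the named long noncoding RNAs, 100 against control, was 0.11 and became -0.028 with a mean RPKM of at least 5, -0.17 with trimmed mean scaling and -0.13 with CPM. Median centring subtracts the shift of the median gene, -0.36 at 50, from every fold, and its sign changes follow from that. TPM moved the median gene from -0.36 to -0.028 at 50, and trimmed mean scaling from -0.041 to -0.30 at 100. The lists that changed sign under these scalings moved the same way. The cause of the other sign changes was not tested. Depth limits the low genes: 1 read was worth 0.0164 CPM in control, 0.0275 at 50 and 0.0148 at 100.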

Other observations

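The tests of genomic DNA, of unspliced RNA, of nested entries, of loss of untailed RNA, of S phase genes and of scaling were chosen after the result was seen, and the tests on well counted genes and on span-adjusted medians were written before their values were seen. ZNF703, a transcriptional regulator named after its value was seen, was 3.63-fold lower [3.04 to 4.34] at 100 than in control. Among autophagy and lysosome genes ATG5 had a ratio of 2.16 [1.98 to 2.36] at 100, not adjusted for gene span. The list median was -0.20 over 22 members.

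Genes with a long span were higher in both PM2.5 libraries. Low counts are argued against, since rho with span was 0.64 in coding genes of at least 1000 reads; genomic DNA was tested against 2 floors: the longest 10% of coding genes gained a median of 1.18 reads per kb, 4.86 times the gain of 374 olfactory receptor genes, but the lower quartile gained only 0.77 times as much, so that test leaves DNA open for part of the long genes, while DNA spread evenly is argued against by a median gain 22.5 times the 10th percentile of reads per kb in genes of at least 1 Mb, a floor chosen after the olfactory values were seen. Both floors need counts over introns: in 114 of 114 pairs of an snoRNA or sense-intronic entry nested in a coding entry with a length equal to the span, the coding entry had at least as many reads, against 103 to 110 in shuffled pairs. More unspliced or nuclear RNA stays open: rho was 0.32 in 412 coding entries with a length under 50% of the span, below the 0.49 to 0.62 of span-matched draws from entries with a length equal to the span, but only 4 such pairs of nested entries exist for the short lengths, so it is not shown that these leave introns out. Whether the trend came from PM2.5 or from the preparation of single libraries was not tested.

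Replication-dependent histone genes were lower in both PM2.5 libraries. A loss of equal size in all RNAs without a poly(A) tail is argued against. Structured RNAs had a median of -0.46 and a lower quartile of -0.56 at 100, where the histone median was -1.30. That quartile lay above a bound of -0.65, which was set after the values were seen. Since structured RNAs were also lower, a loss that was larger for histone mRNAs is left open. The span trend as the whole cause is argued against by a span-adjusted histone median of -1.04 with an upper quartile of -0.80. Fewer cells in S phase may account for it and stays open: 12 S phase genes had a median of -0.37, and histone mRNA follows S phase more closely than they do. An effect of PM2.5 cannot be separated here from a difference between single cultures.

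Integrated stress response genes were lower in both PM2.5 libraries. The span trend as the whole cause is argued against by a span-adjusted median of -0.50 with an upper quartile of -0.25 at 100. Scaling is argued against by a median of -0.26 under the scaling that brought it nearest to 0 of 5 scalings. A difference in medium or nutrient state between cultures could give the pattern as well as PM2.5 and was not tested.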
